A study of Mus musculus with 9 samples.

How the data were processed

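RNA of regulatory T cells (Tregs) from mouse small and large intestinal lamina propria was measured on 9 Affymetrix mouse Gene ST2.0 arrays, 3 each from wild-type (WT), Y3 and Y3/CD103-/- mice, per the labels. The cells were sorted by flow cytometry on a red fluorescent protein linked to Foxp3, and their RNA was amplified and biotin-labelled before hybridization, per the labels' protocols. The deposited values are log2 signal values that the submitters obtained with RMA, per the submitters' processing notes. The log2 scale was read from the values, which ran from 0.115 to 14.05 with array medians between 3.15 and 3.23. The version and settings of RMA, the annotation and the genome build are not given in the sources used here. The spread of the values differed between arrays, with a standard deviation of 1.70 to 1.73 on the WT arrays, 1.87, 1.75 and 1.88 on Y3 arrays 1, 2 and 3, and 1.73 to 1.77 on the Y3/CD103-/- arrays. No hybridization or labelling batch is given in the labels.

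The table held 39137 array features. The platform annotation paired 23521 of them with exactly 1 gene, 1814 with several genes and 13802 with none. Symbols were checked through gene identifiers against a gene table of the GRCm38.p6 assembly, which held 23328 of the features with 1 gene and changed the symbol of 0. Features with several genes or none were left out of the gene tests. Among the 22180 genes, 1082 had more than 1 such feature, and the brightest over all 9 arrays was kept. A gene entered the tests if its value exceeded the median of its own array on at least 3 of the 9 arrays, which left 12792 genes and removed 9388. Gene order was taken from the same GRCm38.p6 table for names and neighbourhood only, since the build behind the arrays' annotation is not given in the sources used here.

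Differences between groups were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. All 9 arrays entered 1 model of group means with no block and shared the estimate of the spread (10.8 degrees of freedom). Every test was 2-sided unless stated, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was said to rise, fall or change at an adjusted p under 0.05. The comparisons were Y3 versus WT, Y3/CD103-/- versus WT and Y3/CD103-/- versus Y3. With no group lacking CD103 alone, no interaction could be fitted. Errors of log2 differences are standard errors from limma, and errors of group values are standard deviations over 3 arrays.

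Gene lists numbered 35 and held 787 genes, of which 614 were tested. Some genes are in several lists, so the results of lists that share members are not independent. They covered Treg, T helper and activation programmes, cytokines and receptors, metabolism, stress, markers of other cells that a sort could hold, and the genes beside Itgae and Il2rb. The 34 lists with at least 5 tested genes were tested with camera in limma at a preset inter-gene correlation of 0.01. camera compares a list with all other genes, so a shift common to all genes does not move it. The lists were tested again with an estimated correlation and with fry, whose p asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. Members were also counted with p-values adjusted over the list alone.

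Genes were named by a rule: in each comparison, the 12 largest rises and the 12 largest falls among genes that passed and whose groups did not overlap, filled to 12 genes by the smallest p where fewer passed. Up to 4 members of smallest p of each list described, members needed for a count of 5 or fewer, and Itgae, Il2rb, Il2ra and Foxp3 were named too. Predicted genes, small RNA genes, receptor families and antigen receptor segments were counted and not named. The groups, comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined.

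Alternatives chosen at that time changed the filter on dim features, the handling of several features per gene, the scaling, the variance model, array weights, the arrays in the fit, the replicate number as a block, the thresholds and the correlation of list genes, and left out each of the 9 arrays in turn. Other alternatives were chosen after seeing the data: Y3 arrays 1 and 3 averaged as 1 sample, the mean of the epithelial list as a covariate, the genes beside Itgae and Il2rb left out, and separate WT arrays as the controls of the 2 Y3 groups. The model and list tests were tested on simulated data with the real genes' means and spreads over 12792 genes. For Y3 versus WT, 66% of 2-fold and 98% of 4-fold changes were recovered with 11 false calls. For Y3/CD103-/- versus WT, 61% of 2-fold and 94% of 4-fold changes were recovered with 9 false calls. For Y3/CD103-/- versus Y3, 66% of 2-fold and 92% of 4-fold changes were recovered with 5 false calls. A list shifted by 0.5 log2 was found in each simulated comparison, and 0 of the other lists among 20 were called. Genes were drawn independently and the lists held random genes. The simulation therefore does not test the preset correlation on lists of genes that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.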

Results

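Gene expression was measured in Tregs sorted from the gut lamina propria of WT, Y3 and Y3/CD103-/- mice, with 3 arrays per genotype. The title of the series names the β chain of the IL-2 receptor (gene Il2rb) and CD103, the αE integrin chain encoded by Itgae, as the dependencies studied. The labels do not describe Y3, which was read as an alteration of the β chain from that title. The comparisons ask which genes differ with Y3, with Y3 and loss of CD103 together, and with loss of CD103 on a Y3 background. Each array held 39137 log2 signal values, and 12792 genes were tested. The labels do not say whether replicates were separate animals or pools, so every p-value measures the spread between these arrays only, and the number of arrays limits the precision. For the median gene, the 95% interval of a log2 difference reached 0.45 to either side.

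The targeted genes were compared first as a check of the labels. Itgae stood at log2 7.93 ± 0.12 (SD, n = 3) in WT, 9.32 ± 0.20 in Y3 and 6.52 ± 0.42 in Y3/CD103-/-, and each Y3/CD103-/- array lay below every other array. It rose 2.63-fold in Y3 against WT (adjusted p = 0.0169). It fell 2.66-fold in Y3/CD103-/- against WT (adjusted p = 0.0159) and 7.00-fold in Y3/CD103-/- against Y3 (adjusted p = 0.000679). The part of Itgae that its feature covers is not given in the sources used here, and signal remained in Y3/CD103-/-. Its rise in Y3 did not pass without WT array 2 (adjusted p = 0.0571), WT array 3 (0.0509), Y3 array 1 (0.0948) or Y3 array 3 (0.113). Its fall against WT did not pass without WT array 1 (0.0538). Il2rb, whose protein carries IL-2 and IL-15 signals, stood at 9.19 ± 0.22 in WT, 8.15 ± 0.32 in Y3 and 8.16 ± 0.31 in Y3/CD103-/-. Its differences from WT, 2.06-fold lower in Y3 (adjusted p = 0.0565) and 2.05-fold lower in Y3/CD103-/- (adjusted p = 0.0590), did not pass. Il2ra, the α chain of the receptor (CD25), stood at 8.15 ± 0.04 in WT, 7.5 ± 0.10 in Y3 and 7.29 ± 0.16 in Y3/CD103-/-. It fell by 0.86 log2 in Y3/CD103-/- (adjusted p = 0.0258), and its difference of -0.65 in Y3 did not pass (adjusted p = 0.0790). The fall of Il2ra passed without Y3 array 2 and did not pass without any 1 of the other arrays (adjusted p from 0.0527 to 0.0809). Foxp3, the defining transcription factor of Tregs, stood at 9.38 ± 0.09 in WT, 9.52 ± 0.17 in Y3 and 9.55 ± 0.06 in Y3/CD103-/-. Its log2 difference was 0.14 in Y3 (95% interval -0.19 to 0.47, adjusted p = 0.658) and 0.17 in Y3/CD103-/- (-0.16 to 0.50, adjusted p = 0.675).

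**Figure D1:**
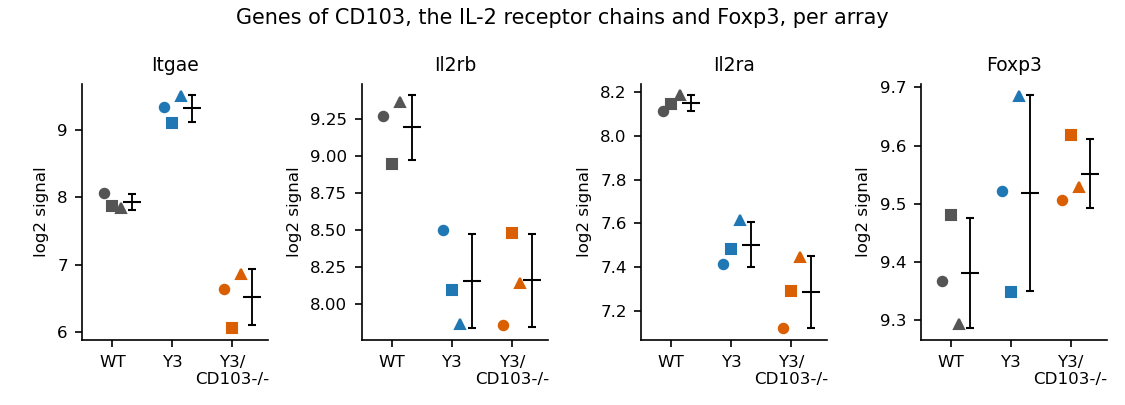
Log2 signal (vertical axes, each with its own range) of Itgae, Il2rb, Il2ra and Foxp3 on each array of WT, Y3 and Y3/CD103-/-; circles, squares and triangles are replicates 1, 2 and 3, and the black dash with its bar is the mean ± SD (n = 3). Itgae lay at 9.11 or above on the Y3 arrays and at 6.86 or below on the Y3/CD103-/- arrays.

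In Y3 against WT, the largest rise was that of Cd7, an immunoglobulin-family surface protein of T and NK cells, at 11.1-fold (log2 3.48 ± 0.20 (SE), adjusted p = 3.61e-05). Il12rb2, a signalling chain of the IL-12 receptor, rose 4.22-fold and Nkg7, a membrane protein of cytotoxic granules, 4.07-fold. The chemokine genes Xcl1 and Ccl5 rose 3.91-fold and 3.75-fold, and Ifng, which encodes interferon-γ, 3.10-fold. Gbp2b, an interferon-inducible GTPase, fell 5.39-fold, and Socs2, a feedback inhibitor induced by STAT5, 4.34-fold. Klrg1, an inhibitory lectin-like receptor of differentiated Tregs, fell 4.13-fold, and Il17rb, the receptor of IL-25, 3.10-fold. Il7r, the α chain of the IL-7 receptor, fell 2.67-fold.

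Of the 12792 genes, 101 changed in Y3, 79 of them up and 22 down, and all 101 had groups that did not overlap. The other named rises were those of Tff1, a trefoil peptide of the mucosa, by 2.05 log2, Mctp2 by 1.97 and Zc3h12c, a ribonuclease of the regnase family, by 1.85. Il1r1, the signalling receptor of IL-1, rose by 1.78, Dapk2, a calmodulin-dependent kinase, by 1.73, and Apol9a by 1.63. The other named falls were H2-Aa, the α chain of a class II MHC molecule (-1.80 log2), the chemokine gene Ccl3 (-1.61), the stress-induced transcription factor Atf3 (-1.51) and Chgb, a protein of secretory granules (-1.46). H2-M2, a class Ib MHC gene (-1.38), Nr1d1, the clock repressor REV-ERBα (-1.31), and Cps1, a urea cycle enzyme (-1.23), fell too. Adjusted p for these genes lay between 0.00753 and 0.0393. H2-Aa is also in the list of macrophage, monocyte and dendritic cell genes, which lay lower in Y3, as did the epithelial list. Whether the falls named here lie in the Tregs or in other cells of the sort cannot be told from these arrays. Gbp2b is 1 of a family of close copies. On a feature shared by Gbp2 and Gbp2b the log2 difference was 0.61 (adjusted p = 0.281 over all features) against -2.43 on the feature of Gbp2b alone. At an unadjusted p under 0.05, 2179 genes differed, 78.9% of them upward, where chance gives 640. The groups did not overlap for 3063 genes (23.9%), where chance gives 10%.

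The median log2 difference of all tested genes in Y3 was 0.15. The split of 79 up and 22 down depended on the scaling, with 46 up and 32 down after quantile normalization and 46 up and 54 down after centring each array on its median. So did the genes called, as 68 of the 101 were still called after quantile normalization and 68 after centring. The share of rises among genes at an unadjusted p under 0.05, 78.9%, was 57.4% after quantile normalization, 39.6% after centring and 51.1% without a filter on dim genes. The count of 101 became 12, 41 and 8 without Y3 arrays 1, 2 and 3, 45 without WT array 2, 64 without WT array 3, and 12 with Y3 arrays 1 and 3, the pair most alike, averaged. Without WT array 1 the count was 119, and 71 of these were among the 101. Of the 101 genes, 7 passed with each of the 9 arrays left out. Of the 24 genes of largest change, Cd7, Nkg7, Ccl5, Il12rb2 and Gbp2b passed with each of the 9 arrays left out. The other 19 did not pass without Y3 array 3 (adjusted p from 0.0523 to 0.21), 16 without Y3 array 1 (0.0815 to 0.171), 11 without Y3 array 2 (0.0501 to 0.107), 8 without WT array 2 (0.0594 to 0.101) and 7 without WT array 3 (0.0711 to 0.102). Without WT array 1 or any 1 of the Y3/CD103-/- arrays, only Il17rb, Cps1, Ccl3 or Atf3 among them did not pass (0.0504 to 0.0791).

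**Figure D2:**
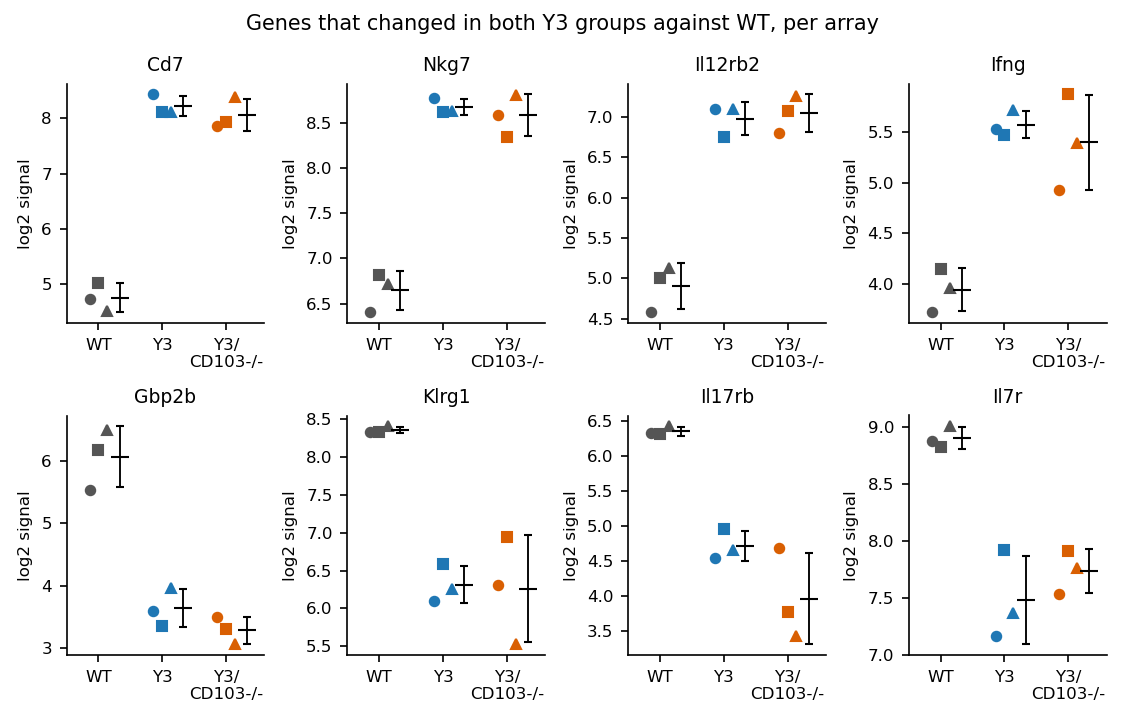
Log2 signal (vertical axes, each with its own range) of 4 genes that rose and 4 that fell in both Y3 and Y3/CD103-/- against WT, per array; circles, squares and triangles are replicates 1, 2 and 3, and the black dash with its bar is the mean ± SD (n = 3). In each panel all Y3 and Y3/CD103-/- arrays lay on 1 side of the 3 WT arrays, with Cd7 at 5.02 or below in WT and at 7.86 or above in the others.

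Genes of the Th1 programme moved up as a group in Y3 by camera (adjusted p = 2.65e-07), and not with an estimated correlation (adjusted p = 0.156; 2.37e-10 to 0.156 over its alternatives). Of 18 measured, 10 rose and 1 fell (12 and 1 adjusted over the list alone). Nkg7, Ccl5, Il12rb2 (2.08 ± 0.20 log2) and Il18rap, a chain of the IL-18 receptor (1.58 ± 0.19, adjusted p = 0.00739), had the smallest p, and Ccl3 was the fall. The list mean went from log2 5.83 ± 0.15 (SD, n = 3) in WT to 6.58 ± 0.05 in Y3. Among Treg transcription factors, Tbx21, which encodes the Th1 factor T-bet, rose by 1.06 log2, Batf by 0.83 and Runx3 by 0.83 (3 of 33 rose, 0 fell; 6 and 2 adjusted over the list alone), and the list did not shift (adjusted p = 0.973). Batf passed in 3 of the 9 fits with an array left out (adjusted p up to 0.171), Tbx21 in 6 (up to 0.148) and Runx3 in 0 (0.0596 to 0.221).

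The Th2 and ST2 tissue Treg programme moved down in Y3 by camera (adjusted p = 2.10e-09). Il1rl1, which encodes ST2, is in the list as fixed and was not analysed, so the fall of the list is no measure of ST2 itself. This list alone held with an estimated correlation (adjusted p = 0.0421; 1.39e-13 to 0.0421 over its alternatives). Of 16 measured genes, Klrg1 and Il17rb fell and 0 rose (9 fell and 0 rose adjusted over the list alone; 9 fell and 0 rose at unadjusted p under 0.05 with limma). Gata3, the master factor of the programme, differed by -0.69 log2 (adjusted p = 0.0551) and Pdcd1 by -0.84 (0.0856). The list mean went from 6.73 ± 0.02 in WT to 6.20 ± 0.02 in Y3.

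The Treg identity list also moved down in Y3, with Socs2, Klrg1 and Nrp1, a surface receptor of thymic Tregs (-0.88 ± 0.17), falling and Itgae rising among 29 genes (8 fell and 2 rose adjusted over the list alone). camera gave an adjusted p of 8.61e-05, and adjusted p = 0.145 with an estimated correlation (2.95e-07 to 0.145 over its alternatives). The fall of Nrp1 passed without WT array 1 (adjusted p = 0.0328) and did not pass without any 1 of the other arrays (0.0616 to 0.21). The median difference of its genes was only -0.02 against a mean of -0.25. IL-2 and STAT5 targets went both ways. That list was fixed without an expected direction for each member, so its test, in any comparison, is no measure of signalling through the receptor. Of 33, Socs2, Il7r and Klrg1 fell, Gzmb, Socs3 and Cdkn1a rose (6 and 7 adjusted over the list alone), and the list did not shift (adjusted p = 0.135). With an array left out, Socs3 passed in 0 of 9 fits (adjusted p from 0.0553 to 0.204), Cdkn1a in 2 (up to 0.231) and Gzmb in 5 (up to 0.135).

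Cytokine receptors and SOCS genes changed in both directions in Y3. Of 32, 6 rose and 3 fell (9 and 8 adjusted over the list alone), led by the rises of Il12rb2 and Il18rap and the falls of Socs2 and Il7r. The list did not shift (adjusted p = 0.294). Apoptosis and survival genes moved up, with Casp4 (1.18 ± 0.15 log2), the apoptosome scaffold Apaf1 (1.39 ± 0.18), Birc2, Bcl2l2 and Cdkn1a rising and 0 of 26 falling (8 up and 1 down adjusted over the list alone; 8 up and 2 down at unadjusted p under 0.05 with limma). camera gave that list an adjusted p of 0.0363, and adjusted p = 0.289 with an estimated correlation (0.000158 to 0.289 over its alternatives). Without WT array 1, 2 or 3 or Y3 array 2 it was 0.0647, 0.0567, 0.0501 and 0.0556. With an array left out, Casp4 and Apaf1 passed in 7 of 9 fits (adjusted p up to 0.0823 and 0.0939), Birc2 in 4 (up to 0.145) and Bcl2l2 in 3 (up to 0.156). T cell receptor activation and immediate early genes moved down relative to the other genes (adjusted p = 0.00256, and adjusted p = 0.289 with an estimated correlation; 4.31e-05 to 0.375, the last with fry). In themselves 15 were higher and 19 lower, with a mean difference of -0.09. Atf3 fell and Batf rose among 34 (3 and 1 adjusted over the list alone). Naive and central memory genes moved down relative to the other genes (adjusted p = 0.0363, and adjusted p = 0.448 with an estimated correlation; 0.00136 to 0.675, the last with fry). Il7r was the only member of 24 that fell (3 fell and 1 rose adjusted over the list alone). The median difference of the naive list was 0.06 and its mean -0.09, and it did not pass without WT array 1 (adjusted p = 0.222) or Y3 array 3 (0.0772).

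Markers of other cells moved with these groups in Y3. Part of this repeats genes named above, since lists share members. Nkg7 and Ccl5 are in the Th1 and the CD8, γδ and NK list, and Ccl5 and Ifng in the Th1 and the conventional CD4 list. Klrg1 and Il17rb are in the Th2 and ST2 and the innate lymphoid list. Il7r is in the naive, the conventional CD4 and the innate lymphoid list. The intestinal epithelial list lay lower, with a median difference of -1.09 log2 over 30 genes (adjusted p = 1.47e-20, and adjusted p = 0.289 with an estimated correlation; 6.54e-27 to 0.289). With limma, 0 of its genes passed, 16 were lower at an unadjusted p under 0.05 and 8 fell adjusted over the list alone, among them Fabp2 (-2.74 ± 0.57) and Car1 (-2.31 ± 0.62). Its mean was 5.35, 6.04 and 5.01 on the WT arrays and 4.73, 3.96 and 4.42 on the Y3 arrays. Macrophage, monocyte and dendritic cell genes lay lower too, with H2-Aa as the only one of 24 to fall, 10 falling and Cd68 rising adjusted over the list alone (adjusted p = 2.07e-10, and adjusted p = 0.145 with an estimated correlation; 1.00e-13 to 0.145). Csf1r, the receptor of the macrophage growth factor, differed by -1.0 log2 (adjusted p = 0.0761). CD8, γδ and NK cell genes moved up, with Nkg7, Ccl5, Xcl1 and the granzymes Gzma (1.22 ± 0.16) and Gzmb (0.89 ± 0.15) rising among 15 (7 rose and 3 fell adjusted over the list alone). camera gave that list an adjusted p of 0.0464, and adjusted p = 0.348 with an estimated correlation (4.41e-06 to 0.348). It was 0.209, 0.0658, 0.0556, 0.0651 and 0.0766 without WT array 1, WT array 2, Y3 array 2, and Y3/CD103-/- arrays 1 and 2. Conventional CD4 T cell genes moved up (adjusted p = 0.00256, and adjusted p = 0.289 with an estimated correlation; 2.95e-05 to 0.289). Ccl5, Ifng and Themis rose and Il7r fell among 13 (5 and 1 adjusted over the list alone), and Themis passed in 4 of the 9 fits with an array left out (adjusted p up to 0.16).

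B and plasma cell genes lay lower in Y3 relative to the other genes (adjusted p = 0.0363, and adjusted p = 0.348 with an estimated correlation; 0.0169 to 0.558, the last with fry). In themselves 6 were higher and 7 lower, with a median difference of -0.01 and a mean of -0.13. Of 13, 0 changed in limma or over the list alone, and 4 were lower at an unadjusted p under 0.05. That call did not pass without WT array 1 (0.1), WT array 2 (0.186) or Y3 array 1 (0.136). Innate lymphoid cell genes lay lower by the test (adjusted p = 0.0363, and adjusted p = 0.289 with an estimated correlation; 0.00121 to 0.289) and by their mean of -0.16, while their median was 0.16. Il7r, Klrg1 and Il17rb fell and Il1r1 rose among the 14 (4 and 1 adjusted over the list alone). The call did not pass without WT array 1 (0.1), WT array 3 (0.172), Y3 array 1 (0.136) or Y3 array 3 (0.0829). Stromal, endothelial and red cell genes did not shift (adjusted p = 0.214), and only 3 granulocyte and mast cell genes were measured, too few for a test.

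The remaining lists did not shift in Y3. Interferon response genes (adjusted p = 0.135), TNF receptor and NF-kB genes (0.136), cell cycle genes (0.789), glycolysis (0.976), oxidative phosphorylation (0.692), lipid synthesis (0.135) and ribosomal protein genes (0.136) had 0 members that passed in limma, with 7, 6, 5, 1, 2, 5 and 4 higher and 0 lower at an unadjusted p under 0.05. Adjusted over the list alone, 4 interferon response genes, 2 cell cycle genes and 1 lipid synthesis gene rose. Itgae rose among the integrins (adjusted p of the list 0.824), with Cxcr3 among the homing receptors (0.278) and with Runx3 among the TGF-β and retinoic acid response genes (0.135). Ccl5, Ifng and Xcl1 rose and Ccl3 fell among the cytokines (0.600), and Gzma, Gzmb and Batf rose and Klrg1 fell among the Treg effector molecules (0.212). Il1r1 rose in the Th17 programme (0.754), Btla in the T follicular programme (0.396), and Btla rose and Klrg1 fell among the inhibitory receptors (0.824). Atf3 fell among the heat shock and dissociation genes (0.191). Beside Itgae, Atp2a3 and Haspin rose (adjusted p of the list 0.212). With an array left out, Btla passed in 1 of 9 fits (adjusted p up to 0.216), Cxcr3 and Haspin in 4 (up to 0.128 and 0.148) and Atp2a3 in 7 (up to 0.0939). Beside Il2rb, 0 of 29 genes passed in limma, with 1 higher and 2 lower at an unadjusted p under 0.05 (adjusted p of the list 0.136). In all, 12 of 34 lists shifted with the preset correlation, 1 with an estimated one and 10 with fry, and 7 shifted without WT array 1. The 12 lists, 4 up and 8 down, depended on the filter. Without a filter on dim genes 11 shifted, 7 up and 4 down, and 7 of them were among the 12. With the filter at the 75th percentile 15 shifted, 3 up and 12 down, and 10 of them were among the 12. Array weights gave 9, all among the 12. Of the 10 lists that fry called, 7 were among the 12. The others were TNF receptor and NF-kB genes (adjusted p = 0.00317 with fry), Treg transcription factors (0.00746) and the genes beside Itgae (0.0262), all upward.

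**Figure D3:**
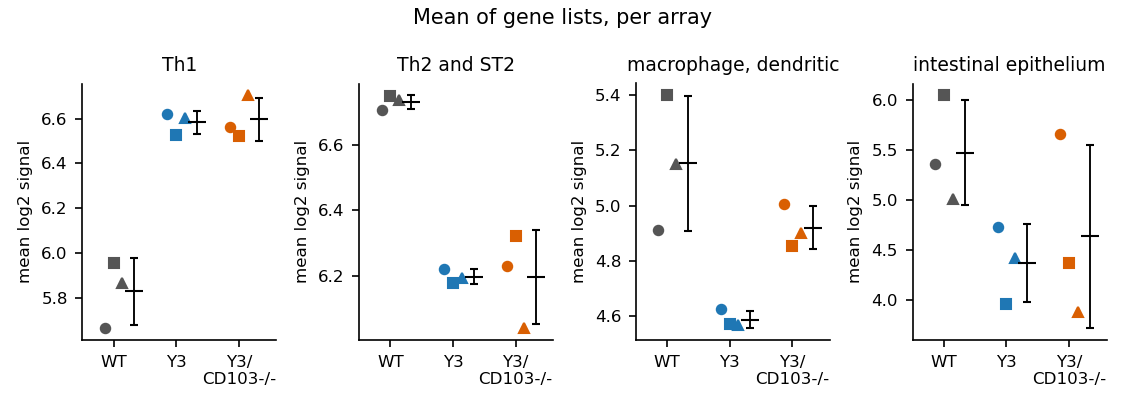
Mean log2 signal over the genes of the Th1, the Th2 and ST2, the macrophage, monocyte and dendritic cell, and the intestinal epithelial list (vertical axes, each with its own range) on each array of WT, Y3 and Y3/CD103-/-; circles, squares and triangles are replicates 1, 2 and 3, and the black dash with its bar is the mean ± SD (n = 3). The Th1 mean was 5.96 or below in WT and 6.52 or above in the other groups, and the epithelial mean of Y3/CD103-/- ran from 3.88 to 5.66.

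In Y3/CD103-/- against WT, Cd7 again had the largest rise, 9.97-fold (log2 3.32 ± 0.20 (SE), adjusted p = 5.91e-05). Il12rb2 rose 4.43-fold, Il1r1 4.18-fold, Nkg7 3.82-fold, Ccl5 3.48-fold and Il18rap 3.08-fold. Gbp2b fell 6.86-fold, Il17rb 5.22-fold, Klrg1 4.27-fold and Il10ra, the ligand-binding chain of the IL-10 receptor, 3.29-fold. Itgae fell 2.66-fold, and Nrp1 fell 2.45-fold.

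Of the 12792 genes, 107 changed in Y3/CD103-/-, 71 up and 36 down, and all 107 had groups that did not overlap. The other named rises were Tff1 by 2.32 log2, C2cd4b by 1.87, Rell1, a relative of the TNF receptors, by 1.72, Apol9a by 1.67, Zc3h12c by 1.64 and Apaf1 by 1.54. The other named falls were Socs2 (-1.51 log2), Prg4, the lubricant lubricin (-1.41), Nr1d1 (-1.37), Cps1 (-1.35), the cytidine deaminase Apobec3 (-1.31) and the lipoxygenase Alox8 (-1.28). Adjusted p for these genes lay between 0.00498 and 0.0447, and the feature shared by Gbp2 and Gbp2b differed by 0.36 (adjusted p = 0.559 over all features). At an unadjusted p under 0.05, 1695 genes differed, 59.6% of them upward, where chance gives 640. The groups did not overlap for 2229 genes (17.4%), where chance gives 10%. The count of 107 was 61, 50 and 53 without WT arrays 1, 2 and 3, 59, 70 and 55 without Y3 arrays 1, 2 and 3, and 49, 50 and 28 without Y3/CD103-/- arrays 1, 2 and 3. Of the 107 genes, 22 passed with each array left out. Of the 24 genes of largest change, Cd7, Il12rb2, Nkg7, Ccl5, Il18rap, Apaf1, Tff1, C2cd4b, Gbp2b, Il17rb, Klrg1, Il10ra, Apobec3 and Alox8 passed with each array left out. Without Y3/CD103-/- array 3, Il1r1, Rell1, Apol9a, Zc3h12c, Socs2, Prg4, Nr1d1, Cps1 and Nrp1 did not pass (adjusted p from 0.051 to 0.147). Without any 1 of the other 8 arrays, 2 to 4 of Itgae, Il1r1, Apol9a, Zc3h12c, Socs2, Prg4 and Cps1 did not pass (0.0506 to 0.118).

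Th1 genes moved up in Y3/CD103-/-, with 8 of 18 rising and 0 falling (13 and 1 adjusted over the list alone; 13 and 1 at unadjusted p under 0.05 with limma), and Nkg7, Il12rb2, Ccl5 and Il18rap had the smallest p. camera gave an adjusted p of 1.02e-10, and adjusted p = 0.114 with an estimated correlation (2.51e-13 to 0.114 over its alternatives). Th2 and ST2 genes moved down (adjusted p = 1.98e-05, and adjusted p = 0.114 with an estimated correlation; 2.13e-06 to 0.114). Of the 16, Il17rb and Klrg1 fell (6 adjusted over the list alone), while Il10, the suppressive cytokine, differed by -0.81 (adjusted p = 0.0688) and Gata3 by -0.60 (0.0847). In the Treg identity list, Nrp1, Klrg1, Itgae, Il2ra, Socs2 and Lrrc32, the docking protein of latent TGF-β, were the 6 of 29 that fell, and 0 rose (13 and 2 adjusted over the list alone; 13 and 3 at unadjusted p under 0.05 with limma). camera gave it an adjusted p of 9.66e-05, and adjusted p = 0.149 with an estimated correlation (3.32e-05 to 0.149). Itgae is the gene targeted in this genotype, so its fall in that list came with the genotype, and the list was not tested without it. Il2rb, read as altered in Y3, is a member too. Lrrc32 passed in 0 of the 9 fits with an array left out (adjusted p from 0.0552 to 0.146).

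Naive and central memory genes moved down in Y3/CD103-/- (adjusted p = 2.56e-05, and adjusted p = 0.306 with an estimated correlation; 1.55e-05 to 0.306). Il7r and Il6st, the gp130 receptor chain, fell among 24 genes (12 fell and 2 rose adjusted over the list alone), and Ccr7, the lymph node homing receptor, differed by -0.85 (adjusted p = 0.0669). The fall of Il6st passed without Y3 array 2 (adjusted p = 0.0434) and did not pass without any 1 of the other arrays (0.0744 to 0.147). That of Il7r passed without Y3 array 1 (0.0405) or 2 (0.0198) and did not pass without any 1 of the other arrays (0.0593 to 0.0989). Cell cycle genes moved up (adjusted p = 0.00133, and adjusted p = 0.332 with an estimated correlation; 0.000232 to 0.332). The topoisomerase gene Top2a (0.85 ± 0.15 log2) was the only member of 33 that rose (2 adjusted over the list alone). TNF receptor and NF-kB genes moved up (adjusted p = 0.0411, and adjusted p = 0.327 with an estimated correlation; 0.00463 to 0.327). Nfkb2 was the only member of 26 that rose (1 adjusted over the list alone). That call did not pass without WT array 1 (0.185), WT array 2 (0.0632), or Y3/CD103-/- array 2 (0.106) or 3 (0.0844). Neither Top2a nor Nfkb2 passed without any 1 of the 9 arrays (adjusted p from 0.0535 to 0.1 for Top2a and 0.0538 to 0.106 for Nfkb2).

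Cytokine receptors and SOCS genes again went both ways in Y3/CD103-/-, with Il12rb2, Il18rap, Il18r1, Il1r1 and Il21r rising and Il10ra, Il2ra, Il7r, Il6st and Socs2 falling among 32 (9 and 9 adjusted over the list alone; adjusted p of the list 0.891). Il21r passed in 4 of the 9 fits with an array left out (adjusted p up to 0.0911). Of IL-2 and STAT5 targets, Gzmb rose and Klrg1, Il2ra, Il7r and Socs2 fell among 33 (7 and 6 adjusted over the list alone; adjusted p of the list 0.328). Apoptosis and survival genes did not shift (adjusted p = 0.0624), with Apaf1, Casp4 and Birc2 rising among 26 (8 up and 1 down adjusted over the list alone). Casp4 and Birc2 passed in 0 of the 9 fits with an array left out (adjusted p from 0.0516 to 0.119 and 0.0636 to 0.147).

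Among other cells, CD8, γδ and NK cell genes moved up in Y3/CD103-/- (adjusted p = 0.000788, and adjusted p = 0.255 with an estimated correlation; 6.66e-07 to 0.255). Nkg7, Ccl5, Gzma (1.29 ± 0.16) and Gzmb (1.07 ± 0.15) rose among 15 (5 adjusted over the list alone). Conventional CD4 genes moved up (adjusted p = 0.0348, and adjusted p = 0.505 with an estimated correlation; 0.00315 to 0.505). Ccl5 and Ifng rose and Il7r fell among 13 (5 and 1 adjusted over the list alone), and Ifng passed in 6 of the 9 fits with an array left out (adjusted p up to 0.0756). That call did not pass without WT array 1 (0.0637), WT array 2 (0.115), Y3 array 2 (0.0729), or Y3/CD103-/- array 2 (0.0623) or 3 (0.128). The epithelial list lay lower, with a median of -0.61 (adjusted p = 1.86e-08, and adjusted p = 0.511 with an estimated correlation; 2.72e-22 to 0.850). With limma, 0 of its 30 genes passed, 8 were lower at an unadjusted p under 0.05, and 3 fell adjusted over the list alone, Fabp2 (-2.60 ± 0.57), Defa24 (-4.65 ± 1.14) and Slc26a3 (-1.76 ± 0.45). Its mean was 5.66, 4.37 and 3.88 on Y3/CD103-/- arrays 1, 2 and 3. Macrophage, monocyte and dendritic cell genes did not shift against WT (adjusted p = 0.242).

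The other lists did not shift in Y3/CD103-/- against WT, with adjusted p from 0.0694 for ribosomal proteins and 0.0755 for lipid synthesis, where the elongase Elovl6 rose by 1.25 log2, to 0.963 for the genes beside Itgae. In the Th17 programme (adjusted p = 0.328), Il1r1, the protease gene Furin and Stat3 rose and the chemokine gene Ccl20 fell. With an array left out, Stat3 passed in 0 of 9 fits (adjusted p from 0.0595 to 0.139), Furin in 1 (up to 0.101), Ccl20 in 2 (up to 0.0774) and Elovl6 in 7 (up to 0.0545). In all, 9 of 34 lists shifted with the preset correlation and 6 with fry. Of those 6, 5 were among the 9, and the other was apoptosis and survival (adjusted p = 0.0321 with fry, upward). With an estimated correlation camera called 0, with 5 at an unadjusted p under 0.05.

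The differences of the 2 Y3 groups from WT were compared gene by gene. Of the 101 genes changed in Y3 and the 107 changed in Y3/CD103-/-, 53 changed in both in the same direction, 40 up and 13 down. Itgae changed in both in opposite directions. Independent lists of these sizes would share 0.438 genes up and 0.0619 down. In 100 simulations all 9 arrays were drawn with no group changed, each gene independently, and 0.01 genes were shared on average and at most 1. With no gene changed very few can be called, so this low sharing was set by the simulation. It is no baseline for lists of 101 and 107 genes. Across genes, which are not independent replicates, the differences correlated at r = 0.685 against 0.5 in the simulations. Their covariance was 0.0852 against 0.0316 ± 0.00108 (SD), a difference of 0.0536. The simulated genes were independent, so that SD leaves out deviations that many genes of an array share. With 1 WT array as the control of a group and the other 2 as that of the other, a split chosen after seeing the data, the covariance was 0.0388 to 0.0547 over the 6 ways (mean 0.0463). The count of shared genes was not taken on such splits, so part of its excess may come from the shared controls. The shared count of 53 was 24 without WT array 2, 26 without WT array 3, 11, 26 and 8 without Y3 arrays 1, 2 and 3, and 34, 31 and 18 without Y3/CD103-/- arrays 1, 2 and 3.

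Between Y3/CD103-/- and Y3, Itgae was the only gene of 12792 that changed, falling by 2.81 ± 0.21 log2 (SE, adjusted p = 0.000679), and it passed with each of the 9 arrays left out. The genes of next smallest p did not pass. Pbx2, a homeobox factor, differed by -1.16 log2 (adjusted p = 0.0730), Tagap1 by -1.41 (0.122), Erdr1 by 1.25 (0.179), Haspin, a mitotic kinase gene that lies inside Itgae in the GRCm38.p6 gene table, by -1.39 (0.182) and the GTPase gene Gbp8 by -0.96 (0.182). H2-Ob, a chain of a class II MHC chaperone, differed by -0.82, the RNA demethylase gene Fto by -1.15, Zmym6 by -0.81, C1ql1 by -1.07, Ccdc58 by -0.86 and Exd2 by -0.99, with adjusted p from 0.193 to 0.265. At an unadjusted p under 0.05, 1267 genes differed, 228 up and 1039 down, where chance gives 640. The share of rises among them, 18%, depended on the scaling and the filter. It was 39.7% after quantile normalization, 47.5% without a filter on dim genes and 65.7% after centring each array on its median. The groups did not overlap for 2374 genes (18.6%), where chance gives 10%. A 2nd gene passed without Y3 array 2 and without Y3/CD103-/- array 2.

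Relative to the other genes, 3 lists moved up in Y3/CD103-/- against Y3. Macrophage, monocyte and dendritic cell genes lay higher (adjusted p = 1.35e-08, and adjusted p = 0.432 with an estimated correlation; 1.28e-10 to 0.432). With limma 0 of 24 passed and 9 were higher at an unadjusted p under 0.05, and H2-Aa (1.25 ± 0.31), C1qb, Csf1r, Apoe and H2-Eb1 rose adjusted over the list alone. Cell cycle genes lay higher (adjusted p = 0.00130, and adjusted p = 0.842 with an estimated correlation; 0.000160 to 0.842). With limma 0 of 33 passed and 3 were higher at an unadjusted p under 0.05, and Foxm1, a driver of mitotic genes (0.75 ± 0.16), rose adjusted over the list alone. That call did not pass without Y3/CD103-/- array 2 (adjusted p = 0.101). The epithelial list lay higher (adjusted p = 0.000179, and adjusted p = 0.855 with an estimated correlation; 2.62e-10 to 0.855). Of its 30 genes, 0 passed in limma, at an unadjusted p under 0.05 or adjusted over the list alone. The list turned downward without Y3/CD103-/- array 1 (adjusted p = 0.795). The other 31 lists did not shift, with adjusted p of 0.992 for Treg identity, 0.680 for IL-2 and STAT5 targets, 0.412 for Th1 and 0.349 for Th2 and ST2 genes, and 0.0759 for naive and central memory genes. camera with an estimated correlation and fry called 0 lists, with 1 and 5 at an unadjusted p under 0.05. The count of 3 was 5 without Y3 array 3 and 6 without Y3/CD103-/- array 1.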

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

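The tests of gene order, of Foxp3 and of Y3 array 2 alone were chosen only after the results they measure were seen. Array features that name several genes or none lay outside the gene tests. Among the 8209 such features bright enough to test, in a fit over all features, 6 passed an adjusted p of 0.05 in Y3 against WT (4 rose and 2 fell) and 19 in Y3/CD103-/- against WT (15 rose and 4 fell). In Y3 all 6 named no gene, and in Y3/CD103-/- 17 named none and 2 named several genes. The 2 that fell in Y3 had the same difference and error (-1.79 ± 0.24 log2), as had 2 that rose in Y3/CD103-/- (2.03 ± 0.29). Each such pair may be the same signal counted 2 times. These signals were set apart because they lie in data that the gene comparisons do not use. Single outlying arrays were not tested by rank, as the test used asks for 4 arrays per group, and the array weights ran from 0.666 for WT array 3 to 3.37 for Y3 array 1.

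Several genes that changed in a Y3 group against WT lie near each other, or near Itgae or Il2rb, in the GRCm38.p6 gene order. Passenger DNA of another strain around a targeted locus could give such a pattern, and the tests leave it open. Beside Itgae, 2 of 21 genes differed at an unadjusted p under 0.05 between Y3/CD103-/- and Y3 (9.52% against 9.9% of the other genes, 1-sided Fisher exact p = 0.63), and beside Il2rb 3 of 29 did in Y3 against WT (10.3% against 17%, 1-sided exact p = 0.893), with upper limits of 30.4% and 27.4%. Within 50 tested genes of either locus 6 of 199 genes had changed (1-sided exact p = 0.0317, Haspin left out), the test being 1 of 6 run, with exact p = 0.0103 with Haspin counted, 0.032 near Il2rb alone, 0.33 near Itgae alone, 0.33 within 25 genes and 0.198 within 100. Of 153 changed genes, 47 had another within 10 tested genes, against a median of 32 in random sets (1-sided permutation p = 0.0208), and without uncharacterised genes 32 of 135 did, against 28 (permutation p = 0.3); genes of related function also lie together, and the strain background of the mice is not given in the sources used here, so these explanations cannot be told apart.

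Of 18 Th1 genes 10 rose and 1 fell in Y3 and 8 rose in Y3/CD103-/-, and of 15 CD8, γδ and NK cell genes 5 and 4 rose, while neither list shifted with an estimated correlation (adjusted p = 0.156 and 0.114 for Th1, 0.348 and 0.255 for the other). Nkg7 and Ccl5 are counted in both lists. CD8, γδ or NK cells stay open as a source, although the cells were sorted on Foxp3-linked fluorescence. The median difference of 8 of their identity genes was -0.25 in Y3 (95% bootstrap interval -0.87 to 0.03) and -0.22 in Y3/CD103-/-. With limma 0 of these genes passed in Y3, and 2 fell there at an unadjusted p under 0.05. The bound set beforehand decides nothing, since 0 γδ genes were measured, 4 of the 8 stood under the median of the WT arrays, Cd8a at 3.05 in WT and 3.18 in Y3 among them, and the brightest, Tyrobp and Fcer1g, are also expressed by macrophages. Above that median, Cd8b1 and Ncr1 differed by -0.25 and -0.19 in Y3 and by -0.62 and -0.27 in Y3/CD103-/-. Neither passed with limma (adjusted p from 0.536 to 0.745). Below it, Cd8a and Klrb1c lay higher in Y3, by 0.13 and 0.25, and did not pass either. A lower share of Foxp3-expressing cells in the Y3 sorts, with more conventional CD4 T cells despite the sort on Foxp3-linked fluorescence, stays open, as the lower 95% limit of the Foxp3 difference was -0.19 and a small loss would be hidden by its high level. This and a change within the Tregs with the Y3 genotype, which was not tested apart from it, cannot be told apart here.

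Among genes at an unadjusted p under 0.05 in Y3 against WT, 78.9% rose. The share was 57.4% after quantile normalization, which evens the spread of values by construction, and 54.6% among 795 genes with Y3 array 2 alone, which was picked for its median, 0.05 above WT against 0.22 and 0.23 on Y3 arrays 1 and 3, and takes its error from the other groups. These tests therefore restate the pattern, and the share was 39.6% after centring each array on its median, 51.1% without a filter on dim genes, and 73.7%, 84.3% and 73.9% without Y3 arrays 1, 2 and 3. Genes too dim to test differed by a median of -0.17. A wider spread left by the normalization and a change of the whole transcriptome with the Y3 genotype, which was not tested apart from it, cannot be told apart here.

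The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, so the share of splits is never under 0.1. In each comparison 1 of the 10 splits, the real one, gave as many genes as were called. The real counts were 101, 107 and 1 for Y3 against WT, Y3/CD103-/- against WT and Y3/CD103-/- against Y3, and the highest counts of the other splits were 3, 1 and 0.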

How the results depend on the processing

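The averaging of Y3 arrays 1 and 3, the epithelial covariate and the omission of the genes beside Itgae and Il2rb were tests chosen only after the data were seen. Counts are given in the order Y3 against WT, Y3/CD103-/- against WT and Y3/CD103-/- against Y3 (101, 107 and 1 genes, with 53 shared by the first pair). They were 1020, 835 and 500 (shared 392) at an unadjusted p under 0.05 and at least 1.5-fold, and 299, 280 and 2 (shared 144) at an adjusted p under 0.1. Without a filter on dim genes the counts against WT were 52 and 54 (shared 29), and with a filter at the 75th percentile 284 and 259 (shared 146). A fit of all features, named or not, called 17 and 50 features rather than genes, of which 6 and 19 named several genes or none. An intensity trend with robust variances gave 346, 309 and 10, array weights gave 346, 60 and 9, and fits of only the 2 groups compared gave 63 and 17 against WT. No pairing of the arrays by replicate number was seen (1 of 9 same-number correlations above 0.1, range -0.044 to 0.107, 4 of 9 arrays closest to their own number). With 3 arrays per group a pairing cannot be excluded. With the replicate numbers as a block the counts against WT were 54 and 55 (shared 24). Averaging Y3 arrays 1 and 3 gave 12 and 62 (shared 12), and the epithelial covariate gave 4 and 16 (shared 4). With that covariate all 101 and 107 genes kept their sign. Their median absolute log2 difference went from 1.16 to 1.10 and from 1.11 to 1.11, and their median SE from 0.19 to 0.24 and from 0.18 to 0.21. On the median the error grew and the difference changed little. Most of these genes rose, so the medians do not show how the falls moved. The epithelial mean was itself lower in both Y3 groups on average, so the covariate cannot separate epithelial content from genotype. Without the covariate, 7 and 22 of the genes passed with each array left out. Between Y3/CD103-/- and Y3 the count was 3 with the mean of a gene's features, and 0 with Itgae and the genes beside the loci left out, by construction. Leaving out 1 array gave 8 to 119, 28 to 70 and 1 to 2 genes (shared 8 to 36), with fewer arrays in each fit. Of the lists, 12, 9 and 3 shifted. An estimated correlation left 1, 0 and 0 (5, 5 and 1 at an unadjusted p under 0.05). Between Y3/CD103-/- and Y3 fry gave 0 lists, no filter on dim genes 5, the filter at the 75th percentile 6 and array weights 5. Leaving out 1 array gave 7 to 12, 7 to 11 and 2 to 6 lists. Apart from the thresholds, the smaller fits and the omission of genes, the cause was not tested. Of the alternative values of named genes that had passed, 476 of 677, 492 of 638 and 20 of 20 passed in the same direction, 201, 146 and 0 no longer passed, and 0, 0 and 0 reversed. The groups of every gene that passed did not overlap, so leaving out an array could not reverse its sign. Signal over background limits dim genes, since 9388 genes were too dim to test.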

Other observations

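The genes in this paragraph were chosen after their values were seen. Of 5 tested neighbours in the GRCm38.p6 gene order that encode receptors of the IL-1 family, 4 lay higher than in WT. Il1rl2, at 2.83 in WT, differed by 0.09 log2 in Y3 (adjusted p = 0.896) and 0.00 in Y3/CD103-/- (0.997) and did not pass. Il1r2, the decoy receptor of IL-1, differed by 1.43 log2 in Y3 (adjusted p = 0.0165) and by 1.07 in Y3/CD103-/- (adjusted p = 0.0533, not passed). The call of Il1r2 in Y3 was lost without Y3 array 1, 2 or 3 (adjusted p up to 0.111). Il1r1 rose by 1.78 and 2.06, Il18r1 by 1.28 and 1.28, and Il18rap by 1.58 and 1.62. With an array left out, Il1r1 passed in 5 and 7 of 9 fits (up to 0.121 and 0.058), Il18r1 in 7 and 8 (up to 0.0995 and 0.0692) and Il18rap in 8 and 9 (up to 0.0523 and 0.0305). Il1rl1, which encodes ST2, was not analysed here.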
